A study of Mus musculus with 2 samples.

How the data were processed

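Nuclei were taken from frozen mouse liver tissue, from a microdissected area of residual tumour in hepatocellular carcinoma (HCC). Libraries were made with the 10x Genomics droplet kit for 3' gene expression. The labels list 2 samples of 1 group, and name no treatment. The deposited values form 1 matrix, whose barcodes all carry the same suffix and name no sample, so it was treated as 1 pooled sample. Whether it holds both samples or 1 of them is not given in the sources used here. No untreated or tumour-free group was analysed here.

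The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode, without normalization. The submitters' processing notes name Cell Ranger 5.0 and the mm10 genome build. Per the file headers, the filtered matrix came from version 5.0.0 and the unfiltered matrix from version 4, and how the 2 samples were combined is not stated. Over the 17169 filtered barcodes, both matrices held equal counts in every entry. The filtered matrix held 95130408 of the 147834570 UMIs, or 64.3%, over 32285 genes. UMIs per filtered barcode ran from 891 to 125991, with a median of 2794.

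Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 5% mitochondrial UMIs. This left 16411 barcodes and removed 758. Scrublet, as implemented in scanpy 1.11.5, called 0 doublets over all barcodes at its automatic threshold of 0.439, so the planned removal of doublets had no effect. A second run among the 9632 barcodes with at least 2000 UMIs, added after the data were seen, called 393. Clustering used 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method (leidenalg 0.10.2) at resolution 1. The gene lists that were to be compared, and a seeded random part of the other genes, 16437 in all, stayed out of the clustering. It gave 25 clusters.

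Clusters were named from markers of 17 cell types, and a class is written as "like" its cell type for that reason. The markers, the gene lists, the filters and the rule for named genes were fixed before the data were examined. The thresholds for turning markers into names were not, and 3 naming rules were tried. The rule used takes free RNA out of each cluster first, and asks for at least 3 markers of a type at 20 CPM or more and at least 2 times the mean of the other clusters that are not near-empty. A cluster was called near-empty when under 10% of its abundant genes differed from the profile of uncalled barcodes. A cluster was called mixed when another lineage also met at least 3 markers, at 50% or more of the leading type's share of markers met. A cluster could thus meet some markers of another lineage and keep its name. Clusters with Pkhd1 of at least 500 CPM and no marker name were kept as a separate unnamed class. The first rule used levels with free RNA left in. The third rule asked for 4 markers and added tests that were built, after the names had been seen, towards names expected by then. It was put back to an alternative for that reason. Names differed between the rules for clusters 3, 8, 10, 14, 24 and 25. Clusters 3 and 10, which make up the hepatocyte-like class, had no name under the first rule. Cluster 14 was cholangiocyte-like only under the rule used. Cluster 8 was macrophage-like under the third rule alone. Cluster 24 was B cell-like under the first and the third. Cluster 25 was stellate-like except under the third.

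Free RNA, which droplets without a nucleus also hold, was measured in uncalled barcodes with at least 500 and under 850 UMIs, 49929 in number, with a mean of 672 UMIs. A profile of barcodes with 1 to 100 UMIs was the planned one and served as an alternative for subtraction.

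For each class, raw UMIs were summed and scaled to a common depth (CPM). Ratios between classes were taken with a pseudocount of 1 CPM on the log2 scale. Folds were taken on CPM without a pseudocount, with exact 95% intervals for the ratio of Poisson counts. Shares carry exact Clopper-Pearson 95% intervals, and a share of 0 an upper limit of 3 counts. Intervals of levels, folds and shares of barcodes or nuclei cover counting error within these pooled nuclei only. The intervals of chromosome 1 shifts came from 2000 bootstrap draws over genes. The interval of the share of chromosome 1 genes is binomial over genes. Genes are not independent replicates, and these intervals describe spread between genes rather than counting error. No interval covers differences between animals. With 1 group there was no test between groups, and nuclei were not used as replicates. No paired analysis was possible because the barcodes carry no sample, and leaving out each sample in turn was not possible for the same reason.

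For each of the 38 gene lists, the median log2 ratio of members with at least 20 UMIs was compared with 10000 random lists of held-out genes, of the same size and matched on level in 25 bins. A list is described as beyond the random lists when it lay in the outer 2.5% on either side. This describes these nuclei and is not a test between animals. HCC-like nuclei were compared with hepatocyte-like nuclei as planned. The comparison of the unnamed Pkhd1-high class with hepatocyte-like nuclei was added after the data were seen.

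The rule for named genes took up to 4 members of each list by size of ratio, and the 12 highest and 12 lowest held-out genes outside the lists with at least 100 UMIs and 20 CPM in the higher class. It also took each list member in the class with its highest level. The rule gave 254 genes over both comparisons. The alternatives were tabulated for the first 2 members of each list beyond the random lists and the genes outside the lists, 103 genes in all. This narrowing was made after the alternatives had been seen, when 140 values over all 254 genes had changed sign. For the narrower set 53 values changed sign. The text names all of these genes in the HCC-like comparison but only part of those in the Pkhd1-high one. Some genes that the rule gave are not reported here, and no other genes took their place.

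Cell cycle transcripts were counted after each nucleus was thinned at random to 2000 UMIs, and a nucleus with at least 3 UMIs of the S and G2M lists was counted as carrying them. Gene positions came from GENCODE release M21 on GRCm38, which held 32158 of the gene identifiers. Levels along chromosomes were set against 9 reference clusters over 7104 genes. These were hepatocyte-, endothelial-, fibroblast-, stellate-, macrophage- and mesothelial-like clusters with at least 90 nuclei and a median of at least 2500 UMIs. The comparison was tested on simulated data, drawn from the measured levels with 200 genes changed 4-fold. Of these, 100% of raised and 98% of lowered genes were found at least 2-fold changed in the HCC-like comparison. The intervals held 94.5% of true ratios, and 93% in the other comparison. Both sides were drawn as Poisson counts from the hepatocyte-like levels, without free RNA, spread between nuclei or clustering. Coverage near 95% was thus built in, and the simulation does not bear on those sources of error.

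Alternatives covered the minimum of UMIs, the doublets, the resolution, the genes and components used for clustering, the mitochondrial limit, scaling by median of ratios, subtraction of free RNA, thinning, the pseudocount and the minimum per member. The naming rules, a second profile of free RNA, a minimum of 2000 UMIs, the second doublet run, other minimums for cell cycle UMIs and a denominator without near-empty clusters and the Pkhd1-high class without cluster 19 were added after the data were seen. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9.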

Results

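Single nuclei from the residual area of mouse HCC were profiled to describe which cells the area held after microdissection. The 2 samples belong to 1 group, and the 1 matrix, whose barcodes name no sample, was treated as pooled. It held 17169 barcodes with 95130408 UMIs, and no value has replicates. The values below come from the 16411 barcodes that passed the filters.

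Under the clustering and naming rule used, hepatocyte-like and cholangiocyte-like nuclei were the largest named classes. Other settings changed this order. With 15 principal components HCC-like nuclei were the largest at 10.97%, and the first naming rule gave no hepatocyte-like nuclei. Hepatocyte-like nuclei, with Apob, Cps1, Hnf4a and Fgb, were 10.7% (10.3 to 11.2; 1764 nuclei) of barcodes. The other markers of that set, Alb, Ttr, Cyp3a11 and Serpina1a, did not pass the rule in clusters 3 and 10. HCC-like nuclei, with Gpc3, H19, Igf2 and Afp, were 4.66% (4.34 to 4.99; 764 nuclei). Their cluster 7 also met the hepatocyte markers Apob, Cps1 and Hnf4a, so these markers do not separate the 2 classes. Cholangiocyte-like nuclei were 9.66% (9.22 to 10.1; 1586 nuclei), and a class with high Pkhd1, a gene of bile duct epithelium, but no full marker set was 15.9% (15.4 to 16.5; 2614 nuclei). The cholangiocyte-like share ran from 4.62% with 15 principal components to 16.4% at 1% mitochondrial UMIs. It was also lower under the other naming rules, which did not name cluster 14 cholangiocyte-like. Of the supporting cells, endothelial-like nuclei were 5.96% (5.60 to 6.33), fibroblast-like 5.52% (5.18 to 5.88), stellate-like 4.49% (4.18 to 4.82) and mesothelial-like 0.841% (0.707 to 0.993). The fibroblast-like share fell to 0.585% at resolution 2 and 0% with 15 principal components, where most of cluster 6 lay in clusters named for smooth muscle. Of the 33 nuclei of stellate-like cluster 25, 32 were called doublets in the second run. Of the immune cells, Kupffer-like nuclei were 2.80% (2.55 to 3.06), macrophage-like 1.54% (1.35 to 1.74) and T cell-like 1.10% (0.949 to 1.27). Of the 459 Kupffer-like nuclei, all of cluster 15, 157 were called doublets in the second run, and more held endothelial markers (259) than Kupffer markers (153). Over the clusterings, the Kupffer-like share ran from 0 to 4.06%, the macrophage-like from 0 to 5.43% and the T cell-like from 0 to 1.15%. The macrophage-like share was higher still under the third naming rule, which named cluster 8 macrophage-like. No cluster was named for B cells, smooth muscle, dendritic cells, neutrophils, NK cells, plasma cells or erythroid cells, so their classes held 0 barcodes, with a counting limit of 0.0183%. That limit holds for the named class only and sets no bound on such cells in clusters of other names. Under alternatives, clusters named for smooth muscle took up to 5.14% and clusters named for erythroid cells up to 5.39%. The mixed cluster 24, with 51 nuclei, nevertheless held the B cell genes Bank1 at 1858 CPM (1645 to 2092) and Pax5 at 590.0 CPM (473 to 728), beside haemoglobin genes and markers from the HCC set. Near-empty clusters took 31.98% (31.3 to 32.7; 5248 barcodes) and mixed clusters 4.78% (4.46 to 5.11; 784 nuclei).

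**Figure D1:**
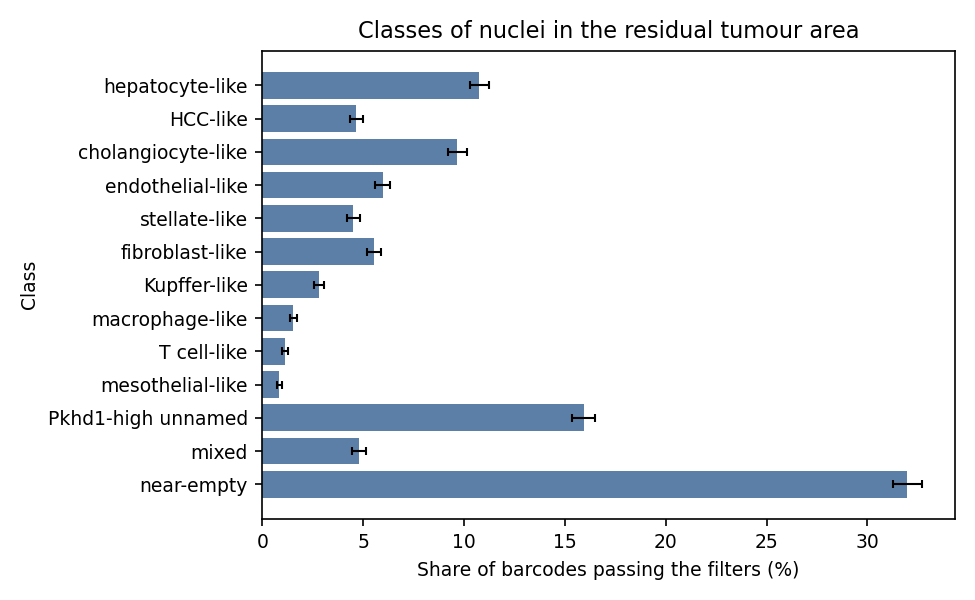
Share of each class among the barcodes that passed the filters, in percent, with bars for classes and whiskers for exact 95% binomial intervals, which cover counting error only. Near-empty clusters take 31.98% and the Pkhd1-high unnamed class 15.9%.

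Markers bore on these names to unequal degree. In HCC-like nuclei Gpc3, an oncofetal proteoglycan, stood at 515 CPM (495 to 535), against 10.9 CPM in hepatocyte-like nuclei and 68.1 CPM in free RNA. H19 stood at 406 CPM (388 to 424) against 251 CPM in free RNA. For Afp, the fetal albumin homologue, 34.6 CPM in HCC-like nuclei lay close to the 33.2 CPM of free RNA. Pkhd1 stood at 2466 CPM (2444 to 2488) in the unnamed class, 4212 CPM in cholangiocyte-like and 1015 CPM in HCC-like nuclei. Cholangiocyte-like cluster 5, with 890 nuclei, also met the HCC markers Gpc3, Spink1 and Igf2bp3. At resolution 0.5 a mixed cluster held 98.2% of its nuclei and 94.9% of those of HCC-like cluster 7. Kupffer-like nuclei held Clec4f at 92.00 CPM, but Cps1, a urea cycle gene of hepatocytes, at 1924 CPM. Clec4f and Cd5l also led mixed cluster 8. The shares moved with the clustering, from 0 at resolution 0.5 to 10.97% with 15 principal components for HCC-like nuclei. Cluster 11 of the Pkhd1-high unnamed class was named HCC-like under 4 alternatives, and most of cluster 12 at resolution 2, so the line between these 2 classes rested on the settings. Cluster 12, with an expected 37.98% of free RNA, lay mostly in clusters named for erythroid cells with 15 principal components (75.8%) and at 1% mitochondrial UMIs (79.9%), and in a near-empty cluster at resolution 0.5 (54.9%). The first naming rule gave no hepatocyte-like class.

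HCC-like nuclei were compared with hepatocyte-like nuclei to describe how these 2 classes differ in the pooled matrix. Its barcodes carry no sample, so differences between samples or animals, if the matrix holds both samples, could not be separated from those between classes. Genes of glycolysis, hypoxia and inflammation were higher in HCC-like nuclei, and genes of bile acid, cholesterol and fatty acid synthesis lower. Of 38 lists, 12 lay above the random lists and 7 below. Against the same reference, cholangiocyte-like clusters 5, 14 and 21 had 12, 14 and 11 lists above and 10 each below. Counts of this size were thus not particular to HCC-like nuclei and may partly reflect the hepatocyte-like reference. The median over all genes with at least 100 UMIs was 0.17 on the log2 scale. Median depth was 5609.5 UMIs in HCC-like and 14965 in hepatocyte-like nuclei, so free RNA weighs more in the former.

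Among the lists above, glycolysis had a median log2 ratio of 1.64, with 10 of 12 members at least 2-fold higher. Pfkp, a phosphofructokinase, was 23.1-fold (20.03 to 26.6) higher and Hk2, a hexokinase, 13.9-fold (11.5 to 16.8). The hypoxia list had a median of 1.48, with 7 of 11 members higher. Its Ndrg1 was 10.2-fold (9.52 to 11.00) higher and Egln3, a prolyl hydroxylase, 6.54-fold (5.29 to 8.09). The NF-kB and inflammatory list had a median of 1.75, with 9 of 13 members higher. Its chemokine Cxcl2 was 30.7-fold (17.5 to 57.6) higher and Ccl2 10.5-fold (7.37 to 15.2). Progenitor and stem cell genes had a median of 1.29, with Cd44 12.1-fold (10.4 to 14.1) and Sox4 11.1-fold (9.03 to 13.7) higher. Apoptosis regulators had a median of 1.36, with the survival gene Bcl2 12.5-fold (10.2 to 15.4) and Pmaip1, which encodes the death factor Noxa, 17.3-fold (7.85 to 41.95) higher. YAP targets had a median of 1.37, with Ajuba 8.74-fold (5.65 to 13.7) and Amotl1 5.64-fold (3.74 to 8.50) higher. NRF2 targets had a median of 1.13, with the transporter Abcc4 13.6-fold (11.6 to 16.03) and Gclc, of glutathione synthesis, 3.29-fold (3.14 to 3.44) higher.

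Extracellular matrix genes had a median of 1.63, with Tnc 22.8-fold (11.1 to 51.2) and Col5a2 6.94-fold (5.27 to 9.14) higher. Their summed level was 366 CPM in HCC-like nuclei, against 1013 CPM in free RNA. The lipid-associated macrophage list, of genes for lipid handling, had a median of 1.51, with Lpl 13.8-fold (11.8 to 16.1) and Cd36 7.24-fold (6.28 to 8.34) higher. That list took 2651 CPM in HCC-like nuclei and 8902 CPM in free RNA. Immune checkpoint ligands had a median of 0.89, with Pvr 3.38-fold (2.80 to 4.07) and Cd274, which encodes PD-L1, 3.73-fold (2.60 to 5.32) higher. Growth factor ligands had a median of 0.83, with Areg, a ligand of the EGF receptor, 35.3-fold (24.1 to 53.5) and Pdgfb 18.6-fold (13.6 to 25.8) higher. In that list 3 of 11 members were at least 2-fold lower. Notch genes had a median of 1.22, with the ligand Jag1 5.31-fold (4.38 to 6.44) and Nrarp 6.91-fold (3.07 to 15.8) higher.

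Among the lists below, pericentral hepatocyte genes had a median of -1.65, with 8 of 12 members at least 2-fold lower. Slc1a2, a glutamate transporter, was 22.7-fold (18.1 to 28.9) lower and the transcription factor gene Tbx3 15.2-fold (8.66 to 29.5). Wnt targets had a median of -1.25, with Rnf43 9.89-fold (7.88 to 12.6) and Axin2 11.4-fold (4.82 to 35.2) lower. Cholesterol synthesis had a median of -1.53, with 13 of 14 members lower. Fdft1, of squalene synthesis, was 3.48-fold (3.07 to 3.96) lower. Bile acid synthesis and transport had a median of -1.15. Its Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 15.4-fold (12.2 to 19.8) lower and Cyp7b1 8.10-fold (7.63 to 8.61). Fatty acid synthesis had a median of -0.95, with Thrsp 8.54-fold (7.10 to 10.4) and the elongase gene Elovl6 5.46-fold (4.87 to 6.15) lower. Complement and coagulation had a median of -0.91, with C8b 4.39-fold (3.78 to 5.12) and Plg 3.18-fold (3.03 to 3.34) lower. The urea cycle had a median of -0.53, with Arg1 2.61-fold (2.46 to 2.76) and Otc 1.74-fold (1.60 to 1.90) lower. The hepatocyte-like class pools cluster 3, led by Sds, and cluster 10, led by Slc1a2, Cyp2c39, Cyp2c38 and Cyp7a1. At resolution 0.5, nuclei of cluster 3 against those of cluster 10 also put the pericentral, Wnt and bile acid lists below the random lists. For these lists, a loss in HCC-like nuclei is thus not separated from differences within the reference.

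Of the genes in no list, Il34 (ENSMUSG00000031750, chromosome 8, 110741829 to 110805924), a ligand of the receptor Csf1r, was 50.2-fold (41.4 to 61.3) higher in HCC-like nuclei. Ccnd3 (ENSMUSG00000034165, chromosome 17, 47505051 to 47599691), which encodes cyclin D3, reached 5142 CPM and was 22.8-fold (22.2 to 23.5) higher. Sctr, the secretin receptor gene, was 29.2-fold (24.3 to 35.2) higher, Sema5a 35.4-fold (30.9 to 40.7) and Lrrk2 35.2-fold (26.6 to 47.3). Eps8l3 and Slc6a20a, with under 10 UMIs in hepatocyte-like nuclei, were 118-fold (58.6 to 279) and 105-fold (53.99 to 234) higher. Elovl7, Cpe, Dab2, St6galnac2 and Zfp827 completed the 12 highest, between 23.00-fold and 30.2-fold. Lowest by log2 ratio with the pseudocount was Kyat3 (ENSMUSG00000040213, chromosome 3, 142701051 to 142746870), 17.98-fold (15.8 to 20.6) lower. The cytochrome genes Cyp2c38 and Cyp2c39 were 18.3-fold (12.03 to 29.2) and 11.3-fold (9.11 to 14.1) lower, and Nr1i3, which encodes the xenobiotic receptor CAR, 9.40-fold (7.69 to 11.6). Calcr, Foxp2, Sult2a8, Ablim3, Ido2 and the antisense genes Tbx3os1 and Tsix were also among the 12 lowest. Of these genes, Cyp2c38, Cyp2c39, Sult2a8 and Nr1i3 were among the leading genes of hepatocyte-like cluster 10. Reads of antisense genes may belong to the gene on the other strand.

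The remaining 19 lists lay within the random lists. They included cell cycle S at 0.86, cell cycle G2M at 0.85, oncofetal genes at 1.03 and the interferon response at 0.41. Of the hepatocyte lists, periportal genes stood at -0.19 and gluconeogenesis at -0.02, and the gluconeogenesis gene Pck1 was among the 10 leading genes of HCC-like cluster 7. Oncofetal genes lay above the random lists under 7 of 15 alternatives and periportal genes below under 6, mostly where the HCC-like class took in or became other clusters. Of the 19 lists beyond the random lists, 8 kept their side under all 15 alternatives that held both classes: bile acid genes, glycolysis, fatty acid synthesis, cholesterol synthesis, hypoxia, NRF2 targets, apoptosis regulators and lipid-associated macrophage genes. The calls for Notch, immune checkpoint ligands and growth factor ligands ended or turned under 10, 7 and 6 of them. Those for Wnt targets did so under 4, and those for NF-kB, extracellular matrix and the urea cycle each under 2. Of the 15, keeping doublets and the third naming rule left both classes unchanged, so no call could end there. At minimums of 1000 and 2000 UMIs the HCC-like class consisted of other nuclei.

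**Figure D2:**
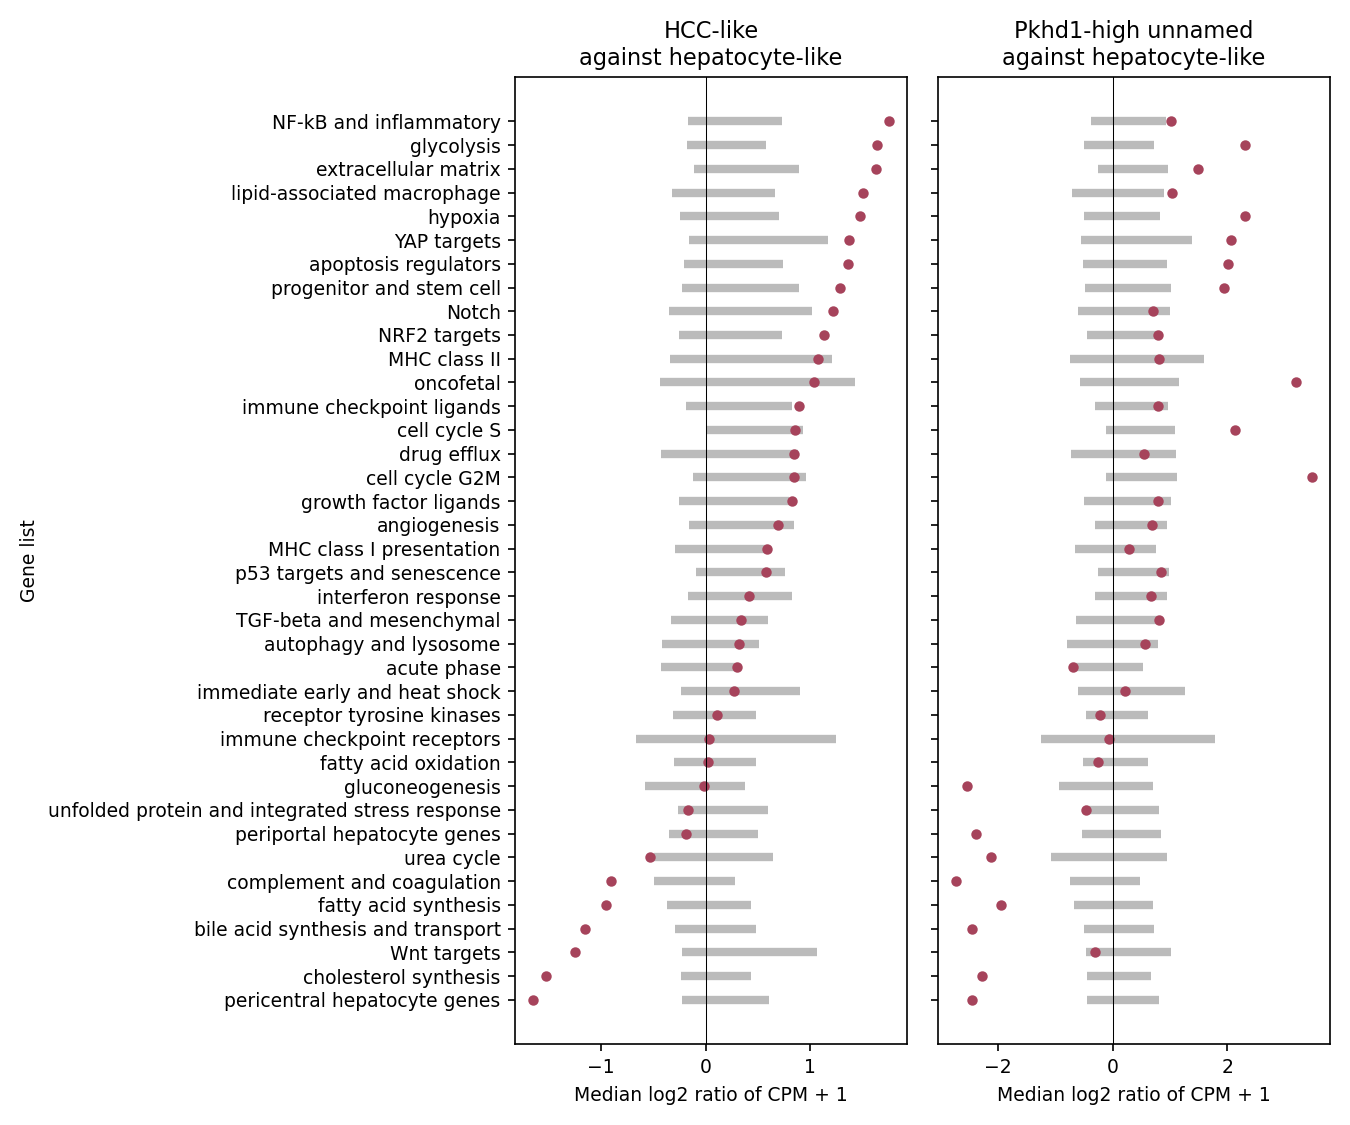
Median log2 ratio of CPM with a pseudocount of 1 for each gene list, as points, with HCC-like (left) and Pkhd1-high unnamed nuclei (right) each against hepatocyte-like nuclei. Grey bars span the central 95% of random lists, and the axes of the panels differ in scale: glycolysis stands at 1.64 and 2.31, pericentral genes at -1.65 and -2.45.

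Pkhd1-high unnamed nuclei were set against the same hepatocyte-like nuclei, a comparison chosen after the data were seen. Cell cycle and oncofetal genes were higher in them, with glycolysis and hypoxia genes, and hepatocyte metabolism was lower. 13 lists lay above the random lists and 8 below, with a median over all genes of 0.24. These counts, too, were near those of cholangiocyte-like clusters 5, 14 and 21. Differences between samples or animals, if the matrix holds both samples, could not be separated from those between classes here either. The G2M list had a median of 3.47, with 20 of 20 members at least 2-fold higher, and the S list 2.14. Cluster 19, with 176 of these nuclei, carried much of this, and without it the medians were 1.32 and 1.17, still above the random lists. Top2a, a topoisomerase of dividing cells, was 42.3-fold (33.4 to 54.3) higher, with a log2 ratio of 1.62 without cluster 19, and the replication gene Mcm6 19.7-fold (14.1 to 28.4). The oncofetal list had a median of 3.20, with Hmga2 59.1-fold (46.7 to 75.9) and the imprinted gene Peg3 41.1-fold (38.8 to 43.7) higher. Glycolysis had a median of 2.31, with Hk2 71.2-fold (60.8 to 83.99) and Pfkp 45.6-fold (40.2 to 51.99) higher. Hypoxia had a median of 2.30, with Ndrg1 54.1-fold (51.1 to 57.4) and Egln3 22.3-fold (19.1 to 26.2) higher. YAP targets had a median of 2.06, with Ankrd1 40.1-fold (35.3 to 45.8) higher. Progenitor genes had a median of 1.94, with Cd44 27.5-fold (24.3 to 31.3) higher. Apoptosis regulators stood at 2.02, extracellular matrix at 1.48, lipid-associated macrophage genes at 1.04, NF-kB at 1.02, TGF-beta and mesenchymal genes at 0.81 and NRF2 targets at 0.80.

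The lists below the random lists held the work of mature hepatocytes. Complement and coagulation had a median of -2.72, with 11 of 13 members at least 2-fold lower. Gluconeogenesis had a median of -2.54, with Pcx, the pyruvate carboxylase gene, 13.6-fold (12.7 to 14.7) lower. Its member Ppargc1a, which encodes the coactivator PGC-1 alpha, was 23.95-fold (23.03 to 24.9) higher, against the list. Bile acid genes stood at -2.45, with the bile salt pump gene Abcb11 20.9-fold (19.1 to 22.9) lower. Pericentral genes stood at -2.45, periportal genes at -2.37, cholesterol synthesis at -2.28, the urea cycle at -2.12 and fatty acid synthesis at -1.93. Of the NF-kB genes, Cxcl1 was 9.68-fold (9.05 to 10.4) lower while Ccl2 was 6.59-fold (4.82 to 9.17) higher. Of the genes in no list, Ahnak2 (ENSMUSG00000072812, chromosome 12, 112772194 to 112802657) was 101-fold (85.9 to 120.1) higher, the basement membrane collagen gene Col4a6 105-fold (85.4 to 129.7) and Dclk1 84.5-fold (70.7 to 102). The receptor gene Grm3, with under 30 UMIs in hepatocyte-like nuclei, was 149-fold (103 to 222) higher, and Zfp804a 86.4-fold (69.6 to 109). Zfp804a was the first of the leading genes of cluster 11. Its ratio turned negative with all variable genes and at a minimum of 2000 UMIs, where most of cluster 11 was named HCC-like. Sult5a1 was 37.9-fold (28.6 to 51.1) lower and Kyat3 26.97-fold (24.8 to 29.4). Of the 21 lists, 14 kept their side under all 17 alternatives that gave a value, while NRF2 targets lost it under 8 and TGF-beta and mesenchymal genes under 7. Extracellular matrix lost it under 5, NF-kB, YAP targets and lipid-associated macrophage genes each under 3, and pericentral genes under 1. Keeping doublets changed no barcodes and could end no call. Other lists gained a side under the 16 alternatives besides resolution 0.5. Unfolded protein and integrated stress response genes lay below under 10, acute phase under 7 and Wnt targets under 6. Immune checkpoint ligands, drug efflux and growth factor ligands lay above under 1 each.

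Cell cycle transcripts were counted to describe which classes carried them. At a common depth of 2000 UMIs, 14.3% (12.9 to 15.8; 322 of 2249) of Pkhd1-high unnamed nuclei held at least 3 UMIs of the S and G2M lists. The share was 2.97% (1.85 to 4.50; 21 of 708) of HCC-like and 0.680% (0.352 to 1.19; 12 of 1764) of hepatocyte-like nuclei. It was 12.4% (6.56 to 20.6; 12 of 97) of mixed cluster 8, 9.09% (3.73 to 17.8; 7 of 77) of T cell-like nuclei and 4.75% (3.71 to 5.97; 69 of 1454) of cholangiocyte-like nuclei. It was 9.13% (5.67 to 13.8; 20 of 219) of macrophage-like and 8.77% (6.34 to 11.8; 40 of 456) of Kupffer-like nuclei. Near-empty barcodes, taken as the background, gave 2.82% (1.47 to 4.88; 12 of 425), a share whose interval includes that of HCC-like nuclei. Each of these 425 held at least 2000 UMIs, against a mean of 672 in uncalled barcodes, so whether they hold free RNA alone stays open. Thinning left out 365 Pkhd1-high unnamed, 56 HCC-like and 0 hepatocyte-like nuclei of lower depth. It left out 4823 near-empty barcodes, 636 of mixed cluster 8 and 104 T cell-like nuclei, so these shares describe their deepest barcodes only. Without thinning the shares were 45.8% of Pkhd1-high unnamed, 22.1% of HCC-like and 40.99% of hepatocyte-like nuclei. Cluster 19 of the unnamed class, with 176 nuclei, led with Top2a, Tpx2 and Mki67 and gave 99.4% (96.9 to 99.99; 175 of 176). Without it the share of Pkhd1-high unnamed nuclei was 7.09% (6.02 to 8.28; 147 of 2073). This pools 17.6% (13.3 to 22.6; 48 of 273) in cluster 12, 6.13% (4.83 to 7.66; 72 of 1174) in cluster 2 and 4.31% (2.86 to 6.21; 27 of 626) in cluster 11. Cluster 12 had an expected 37.98% of free RNA, and thinning left out 354 of its nuclei. The interval of cluster 11 includes the share of cholangiocyte-like nuclei. Free RNA differs between classes and stays open as a source of single UMIs.

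Signalling, matrix and immune genes were set out by class. Extracellular matrix genes summed to 5096 CPM (4864 to 5336) in cluster 22 and 4352 CPM (4278 to 4427) in cluster 6, against 1013 CPM in free RNA. Cluster 22 met 5 fibroblast markers, but its leading genes held none of them and included Notch3 and Rgs5, and it also met the smooth muscle markers Myh11 and Acta2. The angiogenesis list was highest in endothelial-like nuclei at 1939.6 CPM (1898 to 1982), led by Nrp1 at 638 CPM and Nrp2 at 372 CPM. MHC class II genes were highest in macrophage-like nuclei at 1302 CPM (1234 to 1373), against 606 CPM in free RNA. Cd274 was highest in macrophage-like nuclei at 107 CPM (87.9 to 129). Checkpoint receptors were highest in T cell-like nuclei at 634 CPM (564 to 709.9), of which Tox, a regulator of exhausted T cells, took 479 CPM. Pdcd1 and Ctla4 had under 10 UMIs each there. Among growth factor ligands, Igf1 was highest in hepatocyte-like nuclei at 2035 CPM (2019 to 2051), and Nrg1, Areg and Tgfa were highest in HCC-like nuclei, with Nrg1 at 211 CPM (198 to 224). MHC class I genes stood at 1087 CPM in HCC-like nuclei against 3250.1 CPM in free RNA.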

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

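The Malat1 tests of clusters 1 and 4, the test on cluster 21 and the Cps1 test were chosen only after the result was seen. The tests on held-out genes, on windows and on the share of genes were set down first, although the shift of chromosome 1 over all genes was known by then.

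Uncalled barcodes with at least 500 and under 850 UMIs belong to no class and served as the profile of free RNA. They held 33561887 UMIs. Of these, 859924 were of Alb, a hepatocyte transcript, and 48231 were of haemoglobin genes.

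Clusters 1 and 4, with 4261 and 987 barcodes, lay close to the free RNA profile, with 0.0247% and 8.28% of abundant genes at least 2-fold apart from it. The share of nuclear RNA was estimated from Malat1, a transcript kept in the nucleus, on the assumption that nuclei in them would hold as much of it as nuclei of other clusters. In cluster 1 it was 23.98%, above the bound of 18.99%, but its Malat1 level of 38099 CPM lay between the 26729 CPM of that free RNA profile and the 58977 CPM of the planned one, which leaves no nuclear RNA, so free RNA stays open. In cluster 4 it was 8.02%, below the bound of 30.1%, and its Malat1 also lay below the planned profile, so free RNA in droplets without a nucleus may account for it. With 1 group, no biological explanation was tested.

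In cluster 2 of the Pkhd1-high unnamed class, genes of chromosome 1 stood 0.29 higher on the log2 scale, outside the -0.08 to 0.11 of the reference clusters. Genes kept out of the clustering gave 0.31 (0.21 to 0.41, bootstrapped over genes). This argues against an effect of the genes that defined the cluster. Bile duct cluster 21 gave -0.0448 (-0.09 to 0.03), which argues against a general bile duct programme, although cluster 14, cholangiocyte-like by the rule used, gave 0.31. Of the genes, 60.5% (55.99 to 64.9) lay above the reference, so a few strongly changed genes stay open by the bound of 60% set down first, although the interval lies above the 55% they would allow and they would hardly move the held-out median. More copies of the whole chromosome may also be the source, but 79.2% of 24 windows above 0 lay between the bounds set for and against it, and no DNA was measured here. This window share was not particular to cluster 2. It was 87.5% in cluster 14, 83.3% in HCC-like cluster 7 and 75% in endothelial-like cluster 16. In the reference clusters it ran from 29.2% (cluster 23) to 70.8% (fibroblast-like cluster 22).

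Kupffer and hepatocyte transcripts occurred together in cluster 15, the Kupffer-like class, where 157 of 459 nuclei were called doublets in the second run. Cps1 after subtraction of free RNA stayed at 63.3% of its level in hepatocyte-like nuclei. The subtraction took a mean of 672 UMIs per barcode, or 4.02% of the median UMIs of cluster 15, so it could hardly lower Cps1. The value shows only that a free RNA load of this assumed size is too small to be the whole source. If nuclei met at random in droplets, hepatocyte-rich barcodes with Kupffer markers would not far outnumber those with stellate markers, and the ratio was 0.672, from 162 and 241 of 2223 barcodes. In cluster 15 itself 153 barcodes held at least 3 UMIs of Kupffer markers, 157 of stellate and 259 of endothelial markers, so the name is weak. Given the doublet calls and these markers, doublets of hepatocytes with several cell types may make up this class, but the ratio does not decide it. No biological explanation was tested.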

How the results depend on the processing

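The naming rules, the minimum of 2000 UMIs, the second doublet run, the second free RNA profile, the cell cycle minimums, the smaller denominator, the class without cluster 19 and all tests of the Pkhd1-high comparison, also those with settings planned for the other, were chosen after the result was seen. Leaving out a sample was not run, since barcodes carry no sample, and keeping doublets changed nothing, since none had been called. The third naming rule left the HCC-like and hepatocyte-like classes as they were, so the HCC-like comparison could not change under it. The counts below of values that stayed include these settings. The first naming rule gave no hepatocyte-like class and thus no comparison. A list is said to turn when it passed beyond the random lists on the other side, and a gene when a log2 ratio of at least 1 either way changed sign. Of the share values under alternatives, 83 lay outside the counting interval and 87 inside it. Of the list medians, 494 stayed on their side of the random lists, 46 lost it, 56 gained it and 7 turned in the HCC-like comparison. For Pkhd1-high unnamed nuclei these were 586, 30, 28 and 0. Over all genes of the naming rule, 131 values turned in the HCC-like comparison, 86 of them at resolution 0.5, and 9 in the other. The gene values given here cover only the narrower set of 103 genes, part of which the text names. At resolution 0.5 no HCC-like class existed, as 94.9% of the nuclei of cluster 7 lay in a mixed cluster. The rule fixed for that case compared 2 hepatocyte-like clusters, 4 and 11 of that clustering, which held 100% of cluster 3 and 99.5% of cluster 10, so its values show nothing on HCC-like nuclei. At minimums of 1000 and 2000 UMIs, 97.6% and 92.7% of the nuclei of cluster 7 stayed together but were named hepatocyte-like, so the comparison is of other nuclei. The turned genes at 1000 UMIs rest on at most 9 UMIs each in the HCC-like class and show no direction. At 2000 UMIs the HCC-like class was cluster 11 of the Pkhd1-high class, 97.9% of whose nuclei it held. The HCC-like share rose where cluster 11 was named HCC-like too, with all variable genes, with 15 principal components and without the doublets of the second run, and at resolution 2, where most of cluster 12 was. For the other changes the cause was not tested. A share of 0 has a counting limit of 3 barcodes for the class under that setting, and sets no bound on such cells in clusters of other names. Depth limits the HCC-like class, where the free RNA expected from the mean of uncalled barcodes, assumed equal in every droplet, was 11.98% of the median UMIs, against 4.93% in cluster 3.

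With a minimum of 1000 UMIs, the shares of nuclei were hepatocyte-like 17.3%, HCC-like 1.04%, cholangiocyte-like 6.72%, stellate-like 5.19% and macrophage-like 5.43%. Nuclei with cell cycle UMIs there were hepatocyte-like 1.38%, HCC-like 13.9% (only 5 of 36) and Pkhd1-high unnamed 11.98%. Pkhd1-high unnamed nuclei had 8 lists above the random lists. Turned log2 ratios of HCC-like nuclei were growth factor ligands -1.26, Eps8l3 -2.47, Il34 -0.49, Lrrk2 -0.0263, Sema5a -0.53, Slc6a20a -0.25 and St6galnac2 -0.53.

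At resolution 0.5, the shares of nuclei were HCC-like 0%, cholangiocyte-like 4.96%, endothelial-like 4.31%, stellate-like 4.82% and Kupffer-like 4.06%. Further shares were macrophage-like 0% and T cell-like 0%. Hepatocyte-like cluster 4 against 11 gave 6 lists above the random lists. Turned log2 ratios, here between the 2 hepatocyte-like clusters, were fatty acid synthesis 0.24, cholesterol synthesis 0.40, hypoxia -0.28, YAP targets -0.45, apoptosis regulators -0.26, lipid-associated macrophage -0.20, Abcc4 -0.11, Ajuba -0.27, Amotl1 -0.78 and Areg -0.68. Others were Arg1 0.71, Bcl2 -0.55, Calcr 0.27, Ccnd3 -0.30, Cd274 -0.68, Cd36 -1.54, Cd44 -0.26, Col5a2 -1.46, Cpe -0.29 and Dab2 -0.11. Others were Egln3 -1.48, Elovl6 0.19, Elovl7 -0.0752, Eps8l3 -0.00420, Fdft1 0.40, Foxp2 0.40, Ido2 0.0494, Il34 -1.31, Jag1 -0.70 and Kyat3 0.34. Others were Lpl -0.39, Lrrk2 -0.60, Ndrg1 -0.84, Pfkp -0.34, Plg 0.14, Pvr -0.38, Sctr -0.00889, Sema5a -0.63, Slc6a20a -0.15 and St6galnac2 -0.19. Others were Tnc -0.79, Tsix 0.38 and Zfp827 -0.14.

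At resolution 2, the shares of nuclei were hepatocyte-like 9.27%, HCC-like 7.28%, fibroblast-like 0.585% and Kupffer-like 2.41%. Classes absent before were smooth muscle-like 4.27%.

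With clustering on all variable genes, the shares of nuclei were hepatocyte-like 12.8%, HCC-like 7.87%, stellate-like 4.95% and Kupffer-like 0.658%. Nuclei with cell cycle UMIs there were hepatocyte-like 1.33% and Pkhd1-high unnamed 19.7%. Turned log2 ratios of Pkhd1-high unnamed nuclei were Zfp804a -0.44. Classes absent before were erythroid-like 3.68%.

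With 15 principal components, the shares of nuclei were hepatocyte-like 9.52%, HCC-like 10.97%, cholangiocyte-like 4.62%, stellate-like 5.06% and fibroblast-like 0%. Further shares were Kupffer-like 0%, macrophage-like 2.22%, T cell-like 0% and B cell-like 0.914%. Turned log2 ratios of Pkhd1-high unnamed nuclei were Slc1a2 0.57. There the class took in 70.6% of the nuclei of Kupffer-like cluster 15, which holds hepatocyte transcripts, and 81.9% of those of cluster 14. Classes absent before were smooth muscle-like 5.14% and erythroid-like 5.39%. The smooth muscle-like cluster held 90.1% of fibroblast-like cluster 6.

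With at most 1% mitochondrial UMIs, the shares of nuclei were hepatocyte-like 25.8%, HCC-like 6.86%, cholangiocyte-like 16.4%, endothelial-like 4.65% and stellate-like 5.93%. Further shares were Kupffer-like 0%, macrophage-like 2.51% and T cell-like 0%. Classes absent before were smooth muscle-like 0.750% and erythroid-like 3.41%.

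With a minimum of 2000 UMIs, the shares of nuclei were hepatocyte-like 29.1%, HCC-like 6.88%, cholangiocyte-like 15.6%, endothelial-like 7.62% and stellate-like 6.38%. Further shares were fibroblast-like 7.08%, Kupffer-like 1.31%, macrophage-like 0% and T cell-like 0.924%. Nuclei with cell cycle UMIs there were hepatocyte-like 1.79%, HCC-like 5.43% and Pkhd1-high unnamed 18.4%. Pkhd1-high unnamed nuclei had 7 lists above the random lists. Turned log2 ratios of HCC-like nuclei were Cd36 -1.27, Eps8l3 -1.38, Il34 -0.32, Lrrk2 -0.39, Sema5a -0.68, Slc6a20a -1.47 and Tnc -0.32. Turned log2 ratios of Pkhd1-high unnamed nuclei were Zfp804a -0.21.

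Without the doublets of the second run, the shares of nuclei were HCC-like 8.40%, fibroblast-like 5.11% and Kupffer-like 1.63%. Nuclei with cell cycle UMIs there were Pkhd1-high unnamed 18.3%.

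Under the first naming rule, the shares of nuclei were hepatocyte-like 0%, cholangiocyte-like 6.16% and B cell-like 0.311%. Nuclei with cell cycle UMIs there were Pkhd1-high unnamed 12.4%.

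Under the third naming rule, the shares of nuclei were cholangiocyte-like 6.16%, macrophage-like 6.002% and B cell-like 0.311%. Nuclei with cell cycle UMIs there were Pkhd1-high unnamed 12.4%.

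With near-empty clusters out of the denominator, the shares of nuclei were hepatocyte-like 15.8%, HCC-like 6.84%, cholangiocyte-like 14.2%, endothelial-like 8.76% and stellate-like 6.60%. Further shares were fibroblast-like 8.12%, Kupffer-like 4.11%, macrophage-like 2.26% and T cell-like 1.62%.

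With at least 2 cell cycle UMIs, nuclei that held them were hepatocyte-like 4.71%, HCC-like 9.46%, Pkhd1-high unnamed 24.2%, cholangiocyte-like 16.2%, Pkhd1-high unnamed without cluster 19 17.8% and near-empty barcodes as background 12%.

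With at least 5 cell cycle UMIs, nuclei that held them were hepatocyte-like 0.0567%, HCC-like 0.565%, Pkhd1-high unnamed 9.56%, cholangiocyte-like 0.757%, Pkhd1-high unnamed without cluster 19 2.07% and near-empty barcodes as background 0.471%.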

Other observations

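Everything in this part was chosen after the values were seen, and no test was run on it.

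Receptor tyrosine kinases differed in the class where each was highest. Egfr was highest in hepatocyte-like nuclei at 8847 CPM (8814 to 8881), and Erbb4 in cholangiocyte-like nuclei at 1485 CPM (1456 to 1513). Insr was highest in endothelial-like nuclei at 1121 CPM (1089 to 1154) and Fgfr2 in stellate-like nuclei at 1035 CPM (996 to 1074). Mertk, a receptor for the clearance of dead cells, was highest in macrophage-like nuclei at 432 CPM (393 to 474). Hamp, which encodes the iron hormone hepcidin, was highest in hepatocyte-like nuclei at 2366 CPM (2349 to 2384). Tfeb, a regulator of lysosomal genes, was highest in Pkhd1-high unnamed nuclei at 2294 CPM (2272 to 2315), against 60.04 CPM in hepatocyte-like nuclei. Of the hypoxia genes, Vegfa was highest in Pkhd1-high unnamed nuclei at 372 CPM (363 to 381).

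Other chromosomes also stood apart in cluster 2. Chromosome 15 stood at 0.42, with reference clusters from -0.08 to 0.08, and chromosome 4 at -0.33, with reference clusters from -0.06 to 0.11. Of the windows of 20 genes in cluster 2, 92.9% lay above 0 on chromosome 15 and 5% on chromosome 4. In endothelial-like cluster 16 these shares were 85.7% and 10%. On chromosome 10, split at its middle gene, the first part stood at -0.12 in cluster 2 and the second at 0.38. The second part also stood at 0.39 in HCC-like cluster 7, 0.34 in cholangiocyte-like cluster 5 and 0.35 in near-empty cluster 1. In the reference clusters it lay between -0.11 (cluster 10) and 0.05 (cluster 22). This shift covered part of a chromosome and was not particular to cluster 2. HCC-like cluster 7 stood at 0.22 on chromosome 15, 0.23 on chromosome 1 and -0.15 on chromosome 4. Endothelial-like cluster 16 went the same way at 0.13 on chromosome 15 and -0.11 on chromosome 4, both outside the reference clusters. On chromosome 1 it stood at 0.0601, within the reference clusters. It was not a reference only because its median of 2478 UMIs lay under the minimum of 2500, so the reference ranges depend on that minimum. Cluster 14, named cholangiocyte-like by the rule used and left unnamed by the others, stood at 0.31 on chromosome 1, and cholangiocyte-like cluster 5 at -0.08.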
